A study of Drosophila melanogaster with 8 samples.

How the data were processed

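Gene expression was measured in S2R+ cells, a Drosophila melanogaster line of embryonic origin with features of blood cells that adheres to its culture dish. There were 8 samples in 4 groups of 2: unperturbed cells and cells treated with RNAi against koi, lam or msp for 6 days. Total RNA was amplified and labelled with Cy3, and each sample was hybridised to 1 of the 8 arrays of a single-colour Agilent Drosophila slide. The unperturbed samples are listed with no treatment, and no control double-stranded RNA is named in the labels. Changes common to the knockdowns therefore cannot be told apart from a general response to double-stranded RNA. The double-stranded RNA regions are not given in the sources used here. The labels do not state that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

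The deposited array files hold spot intensity as written by Agilent Feature Extraction 10.5.1.1, per the file headers and the submitters' processing notes, with the processed signal already corrected for background. A value table deposited by the authors holds log2 values whose scale and centring are not described. Set against the scanner values, each of its columns was the log2 processed signal minus 1 constant per array, with a largest departure of 0.000508, and the constants lay close to the array's 75th percentile. The column medians were -5.24 and -5.13 (unperturbed), -5.17 and -5.17 (koi), -4.96 and -5.00 (lam) and -5.09 and -5.23 (msp). The table therefore carries no direction of its own, and why its constants differ slightly from the percentile stays unknown. The file of koi replicate 1 had been saved again in another program, with signals kept to 3 significant digits and transcript names in place of probe names, and was matched to the other arrays by feature number.

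For the main values, log2 of the processed signal was taken and the 75th percentile over non-control probes was subtracted on each array. There were 24 spots with outlier marks on individual arrays, and these were left out. Of 15208 non-control probes, 14743 were matched to the RefSeq gene table of assembly Release 6, which was used only for names and for the order of neighbouring genes, and 465 kept the name of the array design. The array design is of an older genome build, per the file headers, so no coordinates are given. Probes well above background on both arrays of at least 1 group were kept, which left 8153 probes and 7546 genes. A gene with several probes was represented by the probe with the highest mean signal, and 1503 genes had more than 1 probe. Among the named genes the probes of Itgbn differed in sign, at 0.13 and -0.10 in koi and 0.04 and -0.24 in lam against unperturbed cells. Levels of different probes were not compared with each other.

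Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 8 arrays, with group means as the only terms. The fit had 4 residual degrees of freedom and 2.75 prior degrees of freedom. The 6 comparisons were each knockdown against unperturbed cells and each pair of knockdowns. Adjusted p-values are Benjamini-Hochberg values from limma within a comparison, and a gene was called at an adjusted p below 0.05, two-sided. Values after ± are standard errors of a log2 difference from limma, from 2 arrays per group, unless marked SD. They rest on a spread pooled over all 4 groups and do not follow the spread of the 2 groups compared. Arrays of the other groups therefore enter each comparison through that spread. A probe not well above background on either array of a group has only a bound there. Its fold is given as at least the ratio of the brighter group's mean to the dimmer group's mean, with each dim array set at the higher of its own value and the lowest signal well above background on it.

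The choices of groups, comparisons, gene lists and alternatives were made before the data were examined, as was the rule for the genes that are named. For each knockdown these were koi, Lam and Msp300, the 10 largest rises and the 10 largest falls among called genes that have a symbol and whose arrays do not overlap, and up to 4 members with the smallest adjusted p from each list that passed or had at least 3 called members. Between knockdowns they were the 5 largest differences in each direction. A gene named outside this rule is said to have been chosen after its values were seen. The 28 gene lists covered nuclear structure, cytoskeleton and adhesion, cell cycle, stress, immunity, signalling, metabolism, and markers of blood cells, testis, germline, neurons, muscle and fat body. The 27 lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, adjusted over 81 tests, and again with an estimated correlation. Members were also tested with adjustment over the list alone. The fry test, which asks whether a list's genes move on balance one way and does not compare them with other genes, was run beside it.

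The scripts were tested on simulated data made from the unperturbed means and the gene-wise spread of the fit to all 8 arrays. That spread was the same for every group, so unequal spread between groups was not tested. In the lam group of the simulation 200 of 7533 genes were changed against its unperturbed group. For that comparison limma recovered 36% of the 50 genes changed by a log2 of 0.5, 84% of those changed by 1 and 100% of those changed by 2 or by 3. Of 168 calls 8 were false, and the unchanged koi and msp groups of the simulation gave 0 calls.

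Each result was recomputed with normexp background correction (offset 50), quantile normalisation, median scaling, no filter on dim probes, a filter on all 8 arrays, the authors' value table, the replicate number as a block, a fit of the 2 compared groups alone, a trended robust prior, array weights, probes of a gene averaged, a fold threshold of 2, and without each array in turn. All 8 arrays lay on 1 slide. The unperturbed and koi arrays formed row 1 and the lam and msp arrays row 2, so the slide row and the group cannot be told apart in the comparisons of lam or msp with unperturbed cells. Koi against unperturbed and lam against msp lie within a row. The unperturbed and lam arrays filled columns 1 and 2 and the koi and msp arrays columns 3 and 4. Slide position and group therefore cannot be fully told apart in any comparison. Because 3 comparisons share the unperturbed arrays, their overlap was also computed in 100 simulations of unchanged groups. In these all 8 arrays were drawn anew around the unperturbed means, with noise independent between genes. The 3 simulated comparisons shared 2 simulated unperturbed arrays.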

Results

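The study asked how altered nuclear shape affects gene expression in Drosophila S2R+ cells. The proteins targeted by RNAi link the nucleus to the cytoskeleton or line it: Klaroid (koi) is a SUN-domain protein of the inner nuclear membrane, Msp300 (msp) a nesprin of the outer membrane, and Lamin (Lam, CG6944) the B-type lamin. Each of the 4 groups had 2 arrays. Of 15208 probes per array, between 7832 and 8646 (51.5% to 56.9%) were well above background, and the 75th percentile of the processed signal lay between 1926 and 2788 units. Over 7533 genes, replicate arrays correlated at Pearson r of 0.994 (unperturbed), 0.997 (koi), 0.993 (lam) and 0.996 (msp), where genes are not independent replicates. The median SD between replicates was 0.09, 0.05, 0.11 and 0.07 log2 in the same order.

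Lam was strongly reduced in the lam arrays and the other targets were not measurably reduced in theirs. The relative log2 signal of Lam was 2.34 ± 0.06 (SD, n = 2) in unperturbed cells and -3.96 ± 0.36 (SD, n = 2) after lam RNAi, a change of -6.30 ± 0.16 that left 1.27% of the signal (limma, adjusted p = 2.25e-05). Lam differed by -0.07 in the koi arrays (adjusted p = 0.936) and by -0.18 in the msp arrays (adjusted p = 0.58). The koi gene is read by a probe designed for CG3287, which joins koi only through the Release 6 gene table. In the koi arrays it differed by 0.08, with a 95% confidence interval of -0.14 to 0.29 (adjusted p = 0.847), although it lay 7.35 log2 above the lowest detected signal. A probe for CG18584, the number given for the koi target, was not well above background on any of the 8 arrays. The Msp300 probe (CG33715) differed by 0.47 ± 0.27 in the msp arrays, with an interval of -0.17 to 1.11 (adjusted p = 0.37), and was dim, 2.02 log2 above the lowest detected signal. This probe read -4.67 in unperturbed replicate 1 and -3.82 in unperturbed replicate 2. It also differed upward in koi (0.55) and lam (0.59), without passing. The msp difference was 0.90 without unperturbed replicate 2 and 0.04 without unperturbed replicate 1, so its size rested on the unperturbed arrays. Another Msp300 probe (CG14035) was not well above background on any of the 8 arrays. A fall of either target transcript was therefore not seen, and it is not known whether these probes lie in the part of the transcript that the RNAi targets. The groups are named below as the arrays labelled koi RNAi and msp RNAi, and each direction drawn for them rests on those labels.

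**Figure D1:**
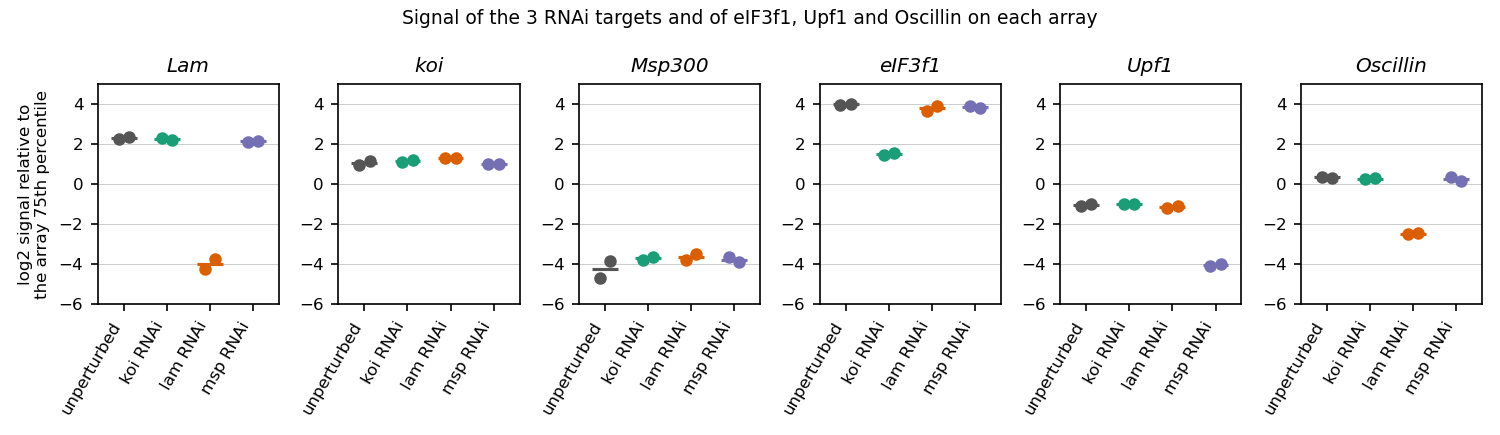
Log2 processed signal relative to each array's 75th percentile (vertical axis) for Lam, koi, Msp300, eIF3f1, Upf1 and Oscillin in the 4 groups, with a point per array and a line at the mean of 2 arrays. Lam fell from 2.34 to -3.96 in the lam arrays, while koi in the koi arrays and Msp300 in the msp arrays were not lower than in unperturbed cells.

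In the arrays labelled koi RNAi, 3 genes passed the test against unperturbed cells. Transcripts of eIF3f1 (CG9769), a subunit of the translation initiation factor eIF3, fell by 2.48 ± 0.10 log2, to a signal 5.57-fold lower (limma, adjusted p = 0.000697). The koi probe itself was not lower in these arrays, and whether the double-stranded RNA also targets eIF3f1 is not known. Acn (CG10473), the fly Acinus, which acts in RNA splicing, fell by 0.98 ± 0.07 (1.98-fold, adjusted p = 0.0158). Hsp70Bb, a heat-inducible chaperone, rose by 1.99 ± 0.18 (3.97-fold, adjusted p = 0.0337). The Hsp70 copies are nearly identical, so their probes may read each other's transcripts and the copy that changed is uncertain. In the heat shock list each copy is counted as a gene of its own, so its counts and tests may hold the same signal repeatedly.

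The heat shock list passed upward in the koi arrays. Its 18 tested members had a median of 1.19 log2, and 16 of them had positive differences (camera, adjusted p = 1.61e-11). With an estimated correlation its adjusted p = 0.747. The heat shock differences of all 3 knockdowns share the same 2 unperturbed arrays, which lay apart for some of these genes (SD of 0.63 for Hsp70Aa, 0.68 for Hsp26 and 0.81 for Hsp70Ba, n = 2). A general response to double-stranded RNA cannot be told apart here, since the unperturbed cells are listed with no treatment. Without unperturbed replicate 2 the list median was 0.95 in koi, 0.56 in lam and 0.97 in msp, and without unperturbed replicate 1 it was 1.51, 1.11 and 1.45, and the list passed each time. Over all genes 1 member rose and none fell, and adjusted over the list alone 11 rose. Members that did not pass over all genes were stv, a co-chaperone of the BAG family, at 1.29 (adjusted p = 0.0668), Hsp68 at 1.35 (adjusted p = 0.094) and Hsp70Aa at 1.78 (adjusted p = 0.118). The list of JAK-STAT and JNK signalling genes had a median of 0.11 over 19 members (camera, adjusted p = 0.0127), with an adjusted p = 0.813 with an estimated correlation. No member passed, either over all genes or adjusted over the list alone: Gadd45 differed by 0.63 (adjusted p = 0.284), egr by 0.34 (0.472), Ets21C by 0.40 (0.591) and upd3, above background on 1 of 2 unperturbed arrays, by 1.28 (0.653). Without unperturbed replicate 1 this list had an adjusted p of 0.292, and its median was 0.20 without unperturbed replicate 2 and 0.17 without koi replicate 1.

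The koi comparison is the smallest of the 6, with 7546 genes tested, 3 called and 570 at an unadjusted p below 0.05. The fall of eIF3f1 passed in every alternative that was run. Acn and Hsp70Bb did not pass without either koi array or either msp array, with adjusted p up to 0.167 for Acn and 0.181 for Hsp70Bb, and Hsp70Bb did not pass without either lam array. The count was 9 without unperturbed replicate 1, 56 without unperturbed replicate 2, and 1 without koi replicate 1, koi replicate 2, msp replicate 1 or msp replicate 2. With median scaling it was 8, of which 5 were higher and 3 lower, and with normexp 9, of which 5 were higher and 4 lower.

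In cells depleted of Lam, LamC (CG10119), the A-type lamin, rose by 2.72 ± 0.16 log2, or 6.60-fold (limma, adjusted p = 0.000638). Swim, a secreted protein that binds Wingless, rose by 3.06 ± 0.35 (8.31-fold, adjusted p = 0.00462), and Cht9, of the chitinase family, by 3.13 ± 0.33 (adjusted p = 0.00364), with 1 of 2 unperturbed arrays above background. Gyc89Db, a soluble guanylyl cyclase subunit, rose by 2.58 ± 0.19 (adjusted p = 0.001). The cytokine gene upd3, whose product activates JAK-STAT signalling, rose by 2.64 ± 0.51 (adjusted p = 0.0299), and Cep290, a ciliary transition zone protein, by 2.66 ± 0.41 (adjusted p = 0.0134), each with 1 of 2 unperturbed arrays above background. Further genes not well above background in unperturbed cells rose by at least 5.35-fold (St4, a sulfotransferase), 4.28-fold (Cyp9h1, a cytochrome P450), 2.52-fold (Cpr49Ac, a cuticle protein) and 1.82-fold (Drsl2, a Drosomycin-like gene), with adjusted p between 0.00281 and 0.0109.

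After lam RNAi, Oscillin (CG6957), the fly glucosamine-6-phosphate deaminase, fell by 2.82 ± 0.09 log2, or 7.05-fold (limma, adjusted p = 3.41e-05). CG31915, chosen after its values were seen, fell by 2.62 ± 0.08, or 6.16-fold (adjusted p = 3.41e-05). Both lie within 5 protein-coding genes of Lam in the Release 6 gene table. Kal1 fell by 1.30 (adjusted p = 0.001), Irk3, a potassium channel, by 1.33 (adjusted p = 0.00676, 1 of 2 lam arrays above background), DCTN4-p62, a dynactin subunit, by 1.21 (adjusted p = 0.0117) and the odorant receptor gene Or67b by 1.18 (adjusted p = 0.0165). The axon guidance ligand gene sli fell by 1.0 (adjusted p = 0.00627), the translational repressor gene glo by 0.96 (adjusted p = 0.00145) and tho2, of the mRNA export complex THO, by 0.91 (adjusted p = 0.0235). Ptr, related to patched, was not well above background on the lam arrays and was at least 1.55-fold lower (adjusted p = 0.00983).

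Of 33 DNA replication genes 7 fell after lam RNAi. The list had a median of -0.30 log2, and 2 of them had positive differences (camera, adjusted p = 1.85e-08). The adjusted p = 0.747 with an estimated correlation. Over all genes no member rose, and adjusted over the list alone 12 fell. They included Prim1, of the primase, at -0.64 ± 0.13, Orc6, of the origin recognition complex, at -0.58 ± 0.11, RnrS, a ribonucleotide reductase subunit, at -0.50 ± 0.09 and the cyclin CycE at -0.49 ± 0.08, with adjusted p between 0.0212 and 0.0319. The mitosis list did not pass, with a median of -0.04 over 37 members (adjusted p = 0.438). Genes of oxidative phosphorylation had a median of -0.11 over 29 members, 1 of them positive (camera, adjusted p = 0.00799), and no member passed over all genes or adjusted over the list alone. That list had an adjusted p = 0.813 with an estimated correlation, and it had medians of -0.06 without unperturbed replicate 1 (adjusted p = 0.171) and -0.05 without lam replicate 1 (adjusted p = 0.221), against -0.20 without unperturbed replicate 2 and -0.22 without lam replicate 2. Median scaling put the medians of the replication and oxidative phosphorylation lists at -0.50 and -0.31, moved with the median of all genes, and both lists passed. Its members ox (-0.55), COX5B (-0.27), ATPsynC (-0.35) and ND-B14 (-0.25) had adjusted p between 0.166 and 0.257.

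Stress lists passed upward after lam RNAi. Heat shock genes had a median of 0.91 over 18 members, 17 positive (camera, adjusted p = 9.52e-05, and adjusted p = 0.747 with an estimated correlation). Over all genes 5 rose, among them Hsp70Aa (1.54), Hsp70Bb (1.39), stv (1.02) and Hsp68 (0.81), and adjusted over the list alone 13 rose. Detoxification and redox genes had a median of 0.33 over 26 members (camera, adjusted p = 0.00106, and adjusted p = 0.813 with an estimated correlation). Of these 8 rose and none fell, and adjusted over the list alone 10 rose. They were mainly glutathione transferases and glutathione synthesis: GstD5 rose by 1.60, Gclc, the catalytic subunit of glutamate-cysteine ligase, by 1.0, GstE6 by 0.93 and GstD9 by 0.77. Without lam replicate 2 the detoxification list had an adjusted p of 0.0579, and with median scaling its median was 0.13 and it passed (adjusted p = 1.1e-05). Apoptosis and DNA damage genes had a median of 0.17 over 24 members (camera, adjusted p = 0.0127). With median scaling the list median was -0.03 (camera, adjusted p = 0.0293). The median of all genes was then -0.20, so the list still lay above it. That list had an adjusted p = 0.747 with an estimated correlation and, without unperturbed replicate 1, a median of 0.10 (adjusted p = 0.0961). Its 4 called members, all higher, were Gadd45 (1.18), Ku80 (0.70) and Irbp (0.64), which encode the Ku proteins of DNA end joining, and p53 (0.52), and adjusted over the list alone 6 rose.

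Members of further lists changed without the list passing. Of JAK-STAT and JNK genes 4 rose, over all genes and adjusted over the list alone: Socs36E, a feedback inhibitor of the pathway, by 1.1 ± 0.11, Ets21C by 0.83, upd3 and Gadd45 (camera, adjusted p = 0.133). Among 14 tested plasmatocyte markers, genes of the main blood cell type, 5 rose and 1 fell, and adjusted over the list alone 6 rose and 3 fell (camera, adjusted p = 0.207, and fry, adjusted p = 0.0339). The rises included Nplp2 (2.20 ± 0.24), fon (1.70 ± 0.11), Tep4 (1.28 ± 0.09) and Tep2 (0.51 ± 0.08). The scavenger receptor gene Sr-CI, chosen after its values were seen, fell by 0.46 (limma, adjusted p = 0.023), and no result without single arrays is given for it. Among 32 integrin and matrix genes the integrin subunits scb (1.55, 1 of 2 unperturbed arrays above background) and if (1.02) and the protease Mmp1 (0.72) rose and LanB1 fell by 0.51 (camera, adjusted p = 0.669), and adjusted over the list alone 3 rose and 3 fell. Of 26 lipid genes bgm rose by 1.97, Hmgs by 0.37 and Lip4 by at least 2.74-fold, the same count of 3 adjusted over the list alone (camera, adjusted p = 0.0881), and Npc2b differed by 1.04 (adjusted p = 0.0863). Of the 12 nuclear lamina and LINC genes LamC rose and Lam fell, with 2 in each direction adjusted over the list alone (camera, adjusted p = 0.933).

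Across all 7546 genes, 565 were called in the lam arrays, 425 higher and 140 lower (75.2% higher), and 1769 had an unadjusted p below 0.05. Of the called genes 180 changed at least 2-fold, 169 upward and 11 downward. Quantile normalisation kept more genes higher than lower, 349 against 202. Of the alternatives that kept the test, only median scaling turned this balance, to 253 higher and 452 lower. That scaling rests on a dim signal: the array medians of the processed signal were 53.3 to 89.0 units, with 51.5% to 56.9% of probes well above background. Median scaling moved the median of all genes by -0.20 log2, and relative to that median, which nearly restores the centring of the main values and is no independent check, 367 were higher and 79 lower. The count was 242 without unperturbed replicate 1, 317 without either koi array, 271 without lam replicate 1, 895 without lam replicate 2 and 375 without either msp array. Of 49 named genes that passed, 25 kept their call without any 1 array, among them Lam, Oscillin, LamC, Swim, Kal1, fon, Tep4, Nplp2 and Socs36E. The calls of upd3, scb, Hsp68, Hsp70Aa, tho2, Orc6, Prim1, RnrS, CycE, p53, Hmgs and Lip4 were each lost in at least 4 of the 8 single-array omissions, with the highest adjusted p from 0.0871 for Hmgs to 0.188 for scb, in most cases without lam replicate 1 or unperturbed replicate 1. The calls of Cep290, Or67b, Ptr, DCTN4-p62, Ets21C, Irbp, Mmp1, Tep2, if, bgm, GstD5 and Gclc were lost without 1, 2 or 3 of the arrays, again lam replicate 1 or unperturbed replicate 1 most often, with adjusted p up to 0.0955 (Or67b).

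**Figure D2:**
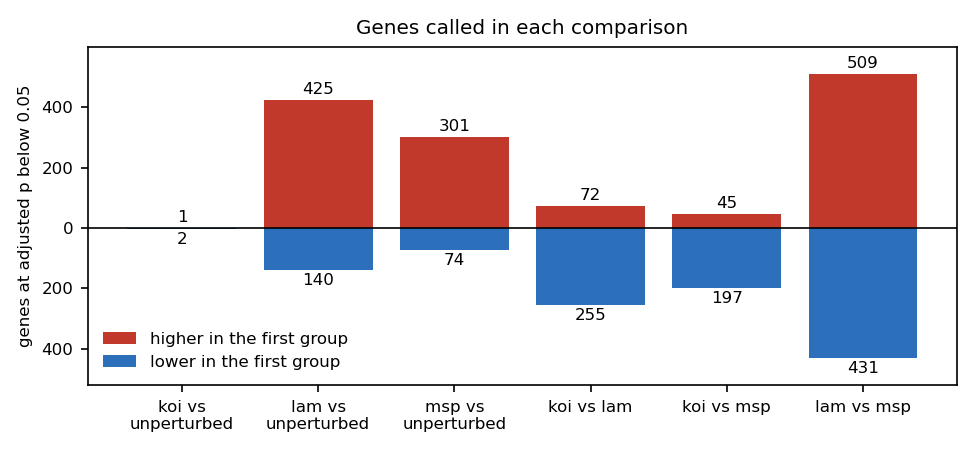
Number of genes called by limma at an adjusted p below 0.05 in each of the 6 comparisons (vertical axis, genes), with bars above 0 for genes higher in the first group and below 0 for genes lower in it. The koi arrays differed from unperturbed cells by 3 genes, the lam arrays by 565 and the msp arrays by 375. Of the alternatives that kept the test, only median scaling turned the lam balance, to 253 higher and 452 lower.

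In the arrays labelled msp RNAi, the change with the lowest adjusted p was a fall of Upf1 (CG1559), the RNA helicase of nonsense-mediated decay, by 3.02 ± 0.09 log2, or 8.10-fold (limma, adjusted p = 6.57e-05). The gene rhea, which encodes talin, the linker of integrins to actin, fell by 2.0 ± 0.17 (3.99-fold, adjusted p = 0.00218), and cv-d, which encodes a lipoprotein, by 1.19 ± 0.07 (adjusted p = 0.000711). Ect3 fell by 1.15 ± 0.13 (adjusted p = 0.00702) and blo by 0.96 ± 0.14 (adjusted p = 0.0135). Genes not well above background on the msp arrays were at least 1.97-fold (PVRAP), 1.78-fold (Ptr), 1.47-fold (BHD, the fly folliculin), 1.2-fold (lectin-28C) and 1.12-fold (Cyp6a2, with 1 of 2 unperturbed arrays above background) lower, with adjusted p between 0.00993 and 0.0468.

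Among the rises in the msp arrays, Try29F, a trypsin-like protease, rose by 1.95 ± 0.09 (3.88-fold, limma, adjusted p = 0.000476), and Rpp21, a subunit of RNase P, by 1.67 ± 0.11 (adjusted p = 0.000711). Gr94a, a gustatory receptor gene, rose by 2.13 ± 0.40 (adjusted p = 0.0345), Gpo2, a glycerol phosphate oxidase, by 1.93 ± 0.32 (adjusted p = 0.0236) and sPLA2, a secreted phospholipase, by 1.83 ± 0.27 (adjusted p = 0.0149), each with 1 of 2 unperturbed arrays above background. The gene yellow-b rose at least 1.88-fold (adjusted p = 0.00382). Heat shock genes had a median of 1.24 over 18 members, 14 positive (camera, adjusted p = 5.75e-06, and adjusted p = 0.747 with an estimated correlation). Over all genes 9 rose, and adjusted over the list alone 10: Hsp70Bb (1.90), Hsp70Ba (1.85), Hsp26 (1.84), Hsp70Aa (1.78), Hsp68 (1.35) and stv (1.18) were among them.

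Other lists in the msp arrays moved less. DNA replication genes had a median of -0.15 over 33 members, 3 positive (camera, adjusted p = 0.00489, and adjusted p = 0.813 with an estimated correlation). No member passed over all genes or adjusted over the list alone: E2f1 differed by -0.87 (adjusted p = 0.109), Mcm7 by -0.35 (0.101), CycE by -0.26 (0.154) and RPA1 by -0.23 (0.132). That list had adjusted p of 0.114 without unperturbed replicate 2 (median -0.07) and 0.132 without msp replicate 1. Oxidative phosphorylation genes had a median of -0.13 over 29 members, 3 positive (camera, adjusted p = 0.029, and adjusted p = 0.813 with an estimated correlation), with no called member and none adjusted over the list alone. Its members cype (-0.34), COX5B (-0.25), SdhB (-0.25) and ND-75 (-0.19) had adjusted p between 0.147 and 0.282. That call was lost with quantile normalisation (adjusted p = 0.102), median scaling (0.0783) and no filter (0.083), and without unperturbed replicate 1 (0.373, median -0.07) or msp replicate 1 (0.105). Markers of crystal cells and lamellocytes, the less common blood cells, had a median of 0.22 over 6 members (camera, adjusted p = 0.0127, and adjusted p = 0.747 with an estimated correlation). Its integrin subunits ItgaPS4 (1.0 ± 0.08) and ItgaPS5 (0.87 ± 0.09) rose, 3 members adjusted over the list alone, PPO3 differed by 0.27 (adjusted p = 0.131), and Ance, not above background on the msp arrays, was at least 1.44-fold lower (adjusted p = 0.321). Its adjusted p was 0.0593 without unperturbed replicate 2 and 0.117 with no filter on dim probes (median 0.05).

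Several msp genes changed in lists that did not pass. The matrix gene vkg, a type IV collagen chain, fell by 0.77 ± 0.12 (limma, adjusted p = 0.0211) together with rhea, while Mmp1 rose by 0.67 and Itgbn differed by 0.36 (adjusted p = 0.0653). Adjusted over the list alone 2 integrin and matrix genes rose and 3 fell (camera, adjusted p = 0.438). Of JAK-STAT and JNK genes Gadd45 (0.72), Ets21C (0.71) and Socs36E (0.62) rose, the same count of 3 adjusted over the list alone, and Ptp61F differed by 0.36 (adjusted p = 0.157). The median of that list was -0.01 although the test pointed upward (camera, adjusted p = 0.541). Of detoxification genes MtnA, a metallothionein, rose by 1.5, GstD5 by 1.18 and Fer1HCH, a ferritin chain, by 0.67, and Cyp6a2 fell, with 6 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.207).

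Of 7545 genes tested in the msp arrays 375 were called, 301 higher and 74 lower (80.3% higher), and 1546 had an unadjusted p below 0.05. At least 2-fold changes were called for 92, of which 82 were higher. The count was 134 without unperturbed replicate 1, 184 without either koi array, 77 without msp replicate 1 and 67 without msp replicate 2. Of 32 named genes that passed, 8 kept their call without any 1 array: Upf1, rhea, cv-d, Try29F, Rpp21, yellow-b, Hsp70Bb and ItgaPS4. For the others the highest adjusted p without 1 array lay between 0.0601 (ItgaPS5) and 0.267 (Fer1HCH), reached in most cases without msp replicate 2.

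**Figure D3:**
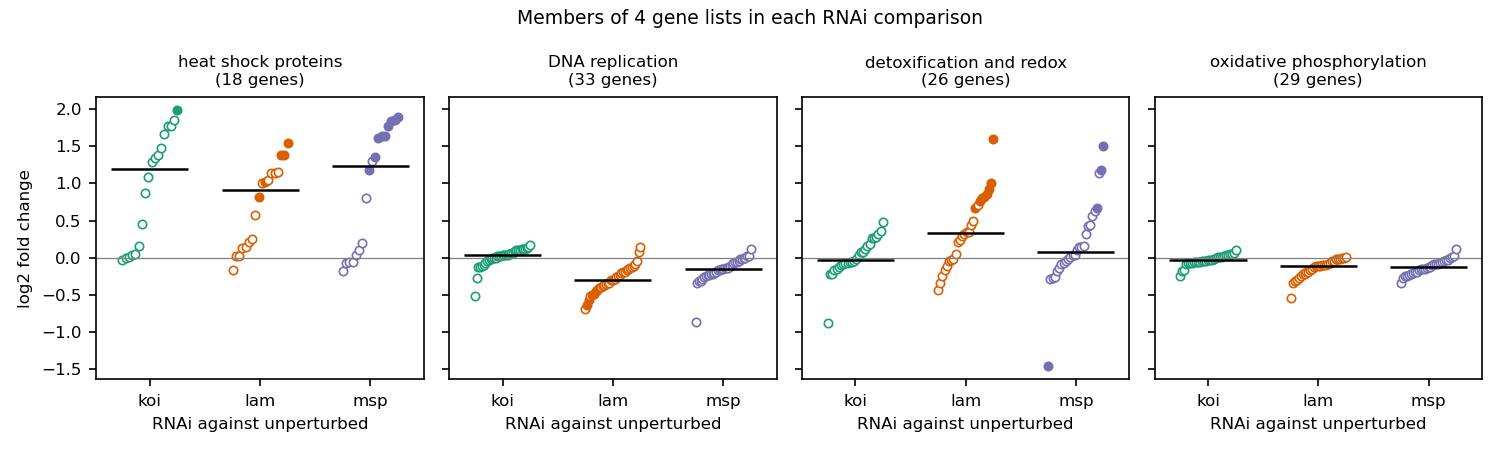
Log2 difference from unperturbed cells (vertical axis) of each tested member of the heat shock (18 genes), DNA replication (33), detoxification and redox (26) and oxidative phosphorylation (29) lists in the koi, lam and msp arrays. Each circle is a gene, filled where it passed an adjusted p below 0.05, and the black line is the list median, which for heat shock genes was 1.19, 0.91 and 1.24.

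Between the koi and lam arrays, Lam was higher in the koi arrays by 6.23 ± 0.16, Oscillin by 2.75 ± 0.09, Kal1 by 1.17 ± 0.09, DCTN4-p62 by 1.14 ± 0.18 and tho2 by 1.06 ± 0.16 (limma, adjusted p from 2.42e-05 to 0.0203). Nazo was lower in the koi arrays, at -2.77 ± 0.14 (adjusted p = 0.000458), as were Cht9 at -3.06 ± 0.33 (adjusted p = 0.00614) and Vha68-3, a subunit of the vacuolar proton pump, at -2.64 ± 0.53 (adjusted p = 0.0448), each of the last 2 with 1 of 2 koi arrays above background. The lectin gene Lectin-galC1 and mag were not well above background on the koi arrays and were at least 4.24-fold and 1.77-fold lower there (adjusted p = 0.0357 and 0.0021). Of these 10 genes all but Vha68-3 and Lectin-galC1 (adjusted p = 0.101 and 0.092) had also passed in the lam arrays against unperturbed cells. In all 327 genes differed, 72 higher and 255 lower in the koi arrays, and 1442 had an unadjusted p below 0.05. Quantile normalisation gave 102 higher and 216 lower, and median scaling 259 higher and 163 lower, with the median of all genes at 0.19. Relative to that median, close to the main centring again, 33 were higher and 243 lower. The count was 86 without koi replicate 1, 87 without koi replicate 2, 133 without lam replicate 1, 656 without lam replicate 2 and 185 without either msp array. Calls of DCTN4-p62, tho2, Lectin-galC1 and Vha68-3 were lost without single arrays, with adjusted p up to 0.133, 0.129, 0.195 and 0.189.

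Between the koi and msp arrays, Upf1 was higher in the koi arrays by 3.04 ± 0.09 (limma, adjusted p = 6.24e-05), rhea by 1.78 ± 0.17 (adjusted p = 0.00476), the receptor tyrosine kinase gene Alk by 1.53 ± 0.27 (adjusted p = 0.0359, 1 of 2 msp arrays above background) and Had2 by 1.12 ± 0.21 (adjusted p = 0.0427). Cyp9h1 was above background on 1 koi array and on neither msp array (adjusted p = 0.0198), and its bound gave no fold. On the other side eIF3f1 was lower in the koi arrays, at -2.34 ± 0.10 (adjusted p = 0.00034), followed by Try29F at -1.80 ± 0.09, Rpp21 at -1.59 ± 0.11, Snup, the snurportin gene, at -1.56 ± 0.14 and ste24b, a CAAX protease gene, at -1.48 ± 0.09 (adjusted p from 0.000684 to 0.00322). In all 242 genes differed, 45 higher and 197 lower in the koi arrays, with 1258 at an unadjusted p below 0.05. The count was 49 without koi replicate 1, 41 without koi replicate 2, 65 without msp replicate 1 and 44 without msp replicate 2. Calls of Cyp9h1, Alk and Had2 were lost without single arrays, with adjusted p up to 0.154, 0.203 and 0.272.

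The lam and msp arrays, which lie in the same slide row but in different columns, differed most in the main fit. With array weights koi against msp gave more calls, 708 against 636 for lam and msp. Lam was lower in the lam arrays at -6.12 ± 0.16 and Oscillin at -2.75 ± 0.09 (limma, adjusted p = 2.74e-05 and 3.01e-05). Try29F (-1.94 ± 0.09), sPLA2 (-1.81 ± 0.27) and Rpp21 (-1.79 ± 0.11) were also lower there (adjusted p from 0.000231 to 0.00807), sPLA2 with 1 of 2 lam arrays above background. Nplp2 was higher in the lam arrays by 3.05 ± 0.24 (adjusted p = 0.000873). Cht9, Cyp9h1, Vha68-3 and Cpr49Ac were not well above background on the msp arrays and were at least 8.78-fold, 4.45-fold, 3.22-fold and 2.62-fold higher in the lam arrays (adjusted p from 0.000631 to 0.007). In all 940 genes differed, 509 higher and 431 lower in the lam arrays, with 2161 at an unadjusted p below 0.05. The balance turned with quantile normalisation (420 higher, 517 lower), without lam replicate 1 (230 higher, 257 lower) and with median scaling (259 higher, 674 lower). Median scaling put the median of all genes at -0.14, and relative to it, close to the main centring again, 373 were higher and 349 lower. The count was 542 without either koi array, 487 without lam replicate 1, 428 without msp replicate 1 and 257 without msp replicate 2. Calls of Vha68-3 and sPLA2 were lost without single msp arrays, with adjusted p of 0.0615 and 0.0545.

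The lam and msp arrays shared 83 genes called in the same direction, 72 higher and 11 lower, and 7 genes were called in opposite directions. Independent lists of these sizes would share 17.0 higher and 1.37 lower genes. Unchanged groups, simulated with unperturbed arrays that were redrawn as well, shared 0.01 on average and at most 1 in 100 draws. Unchanged groups give almost no calls, so that value does not show how many shared genes the common unperturbed arrays add to real changes. The simulated noise was independent between genes, so joint departures of many genes on the real unperturbed arrays were not in it either. Shared rises included Hsp70Bb, Hsp70Aa, Hsp26, stv, GstD5, Gr94a and yellow-b, and shared falls included cv-d, sli and Ptr. Across genes, which are not independent replicates, the log2 differences of lam and msp correlated at Pearson r = 0.32 (Spearman rho = 0.35), against 0.50 (0.46 to 0.55) in simulation. Unchanged groups of equal spread that share an unperturbed group correlate near 0.50 by construction. Changes particular to 1 knockdown lower the correlation, so the lower value does not show that lam and msp were unlike. Their covariance was 0.0426 against a simulated 0.0119, a difference of 0.0307. For koi and lam the correlation was 0.47 and the covariance difference 0.0329, and for koi and msp 0.51 and 0.0258. The simulation gave every group the same spread, so these differences may still hold a part that comes from sharing the real unperturbed arrays. With a separate unperturbed array for each knockdown the lam and msp covariance was 0.0232 or 0.0201. It was 0.0216 or 0.0264 for koi and lam and 0.0157 or 0.0176 for koi and msp, pairs that lie in different slide rows. That split removes the sharing from the covariance at 1 unperturbed array per knockdown, but the shared calls were not split, so part of the 83 may come from the shared unperturbed arrays. The lam and msp arrays also share slide row 2 while the unperturbed arrays lie in row 1, so the row stays open for the shared calls, although among those named Hsp70Bb also rose in the koi arrays of row 1 (1.99), where Hsp26 (1.85), Hsp70Aa (1.78) and stv (1.29) did not pass. Each knockdown was compared with cells listed with no treatment, so a general response to double-stranded RNA also stays open for the shared calls. The shared count was 33 without unperturbed replicate 1, 174 without unperturbed replicate 2, 40 without either koi array, 16 without msp replicate 1 and 17 without msp replicate 2.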

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

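Of the tests below, the comparisons on left-out arrays and the direct tests of msp against koi and lam for decay targets and the interval of the Msp300 change were chosen after the results were seen, as were Smg5, Smg6, Upf2, tra, tra2, Pabp2 and CG31915 as genes to follow.

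There were 7 genes called in opposite directions in the lam and msp arrays, with a direct test of the difference between these groups within their slide row, though across columns. CG4313 differed by -1.568 log2 between lam and msp (limma, adjusted p = 0.000231), at -0.48 in lam and 1.08 in msp against unperturbed cells. CG18547 differed by 1.514 (adjusted p = 0.00101), at 0.84 in lam and -0.67 in msp. CG31817 differed by 1.408 (adjusted p = 0.000873); it was not well above background on the msp arrays, so that it was at least 1.73-fold higher in lam, and 1 of 2 unperturbed arrays was above background. CG10936 differed by -1.054 (adjusted p = 0.00078), at -0.35 and 0.71. CG5359 differed by -1.019 (adjusted p = 0.000954), at -0.38 and 0.64. The thymosin gene cib differed by 0.9838 (adjusted p = 0.00161), at 0.39 and -0.59. SkpB, of the SCF ubiquitin ligase family, differed by 0.8607 (adjusted p = 0.002), at 0.39 and -0.47. Being chosen for opposite calls, these genes were bound to differ between lam and msp. The opposite calls themselves were weak: in lam, cib, CG10936, CG5359 and SkpB were near the threshold (adjusted p = 0.0487, 0.0435, 0.043 and 0.0404) and lost that call without each of the 8 single arrays, with adjusted p up to 0.134, and CG4313, CG18547 and CG31817 lost their lam call without 1 to 3 of them, with adjusted p up to 0.0848 (CG31817, without lam replicate 1). In msp the call of CG4313 held without any 1 array, while CG18547 and SkpB lost theirs without 5 of them, cib and CG31817 without 3 and CG10936 and CG5359 without 2, with adjusted p up to 0.164, 0.181, 0.127, 0.121, 0.0597 and 0.0866, highest without unperturbed replicate 1 for CG18547 and without msp replicate 2 for the others.

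In the arrays labelled msp RNAi, Upf1 fell by 3.02 log2 while the Msp300 probe was not lower. A loss of Upf1 function, by an unintended target of the double-stranded RNA or by another RNA in these wells, is a candidate explanation for part of the msp profile: it would raise Gadd45 and Oda, transcripts kept low by nonsense-mediated decay. Both passed in the msp arrays, Gadd45 at 0.723 (adjusted p = 0.0399) and Oda at 0.85 (adjusted p = 0.00702), and Smg5 (1.03), Smg6 (0.77) and tra (1.5) rose too, but Upf2 (0.14), tra2 (-0.03) and Pabp2 (-0.15) did not pass (adjusted p = 0.822, 0.909 and 0.419), and apart from tra these calls were lost without 2 to 7 of the 8 single arrays, with adjusted p up to 0.223 (Smg5, without msp replicate 2). The explanation stays open: against lam, in the same slide row, Oda, Smg5, Smg6 and tra were higher in msp (adjusted p = 0.00807, 0.0164, 0.0245 and 0.000873), and against koi Oda and tra were (adjusted p = 0.0165 and 0.00142) while Smg5 and Smg6 did not pass (0.0978 and 0.0511), but Gadd45 did not differ detectably from koi (-0.09, adjusted p = 0.791) and rose by 1.18 in lam, where Upf1 was at -0.12 (adjusted p = 0.464). The Msp300 probe lay 2.02 log2 above the lowest detected signal in unperturbed cells, short of the 3 set in advance for a case against a fall hidden by a dim probe, but it lay 2.54 above it in msp cells and the interval of -0.17 to 1.11 for the change argues against a large hidden fall at this probe, while an effect of Msp300 loss itself on Upf1, transcripts that this probe does not read and a wrong label were not tested.

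Rises outnumbered falls in both the lam and msp arrays, which share a slide row and cannot be told apart from it against unperturbed cells. The 425 genes that rose in lam lay a median of 0.612 log2 above the msp arrays of the same row, which decides nothing because the lam arrays had chosen them, but genes chosen without 1 array also lay above the other group of the row on that array, by medians of 0.90 and 0.40 in lam (207 and 549 genes, without replicate 1 and without replicate 2) and of 0.95 and 1.01 in msp (70 and 62 genes), the lowest being 0.3995. A uniform row shift as the whole source of these rises is argued against by this, while a part of them may still come from the row. The same genes lay 1.2, 0.51, 1.06 and 1.19 above unperturbed cells. They had been called against those unperturbed arrays, so these distances do not measure a part that comes from the row. The lam arrays lie in columns 1 and 2 and the msp arrays in columns 3 and 4, so a shift that differs along the row was not tested. Under normexp rises made up 78.5% of the calls in lam and 86.0% in msp, past the limit set in advance for a case against leftover background. Normexp itself takes the local background read on each array, whose medians were 109 to 122 in row 1 and 85 to 99.5 in row 2. An error in that reading would stay under normexp, so these shares do not exclude a background cause. Spike-in spots were lower in row 2 by a median of -0.415 (6 of 10 probes, -0.44 to -0.37 between probes), neither raised there nor within the limit of 0.2 set in advance for a case against the row. The spread between arrays was about as large, with SD of 0.19 to 0.34 in row 1 and 0.37 to 0.55 in row 2. Against unperturbed cells these probes were at -0.72 to -0.56 in lam and -0.47 to -0.22 in msp. The row difference of the 3 dimmer probes minus that of the 3 brighter ones was -0.003 (95% interval -0.109 to 0.104). A row difference in the amount of RNA or of spike-in and the choice of scale (35.9% rises in lam with median scaling) stay open.

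Oscillin and CG31915 fell with Lam in the lam arrays, by 2.82 and 2.62 log2. In the Release 6 gene table both (2 of 2) lie among the 5 nearest protein-coding genes on either side of Lam, Oscillin next to it and CG31915 at the fifth place, which is consistent with an effect tied to position. The 4 other tested neighbours all lie between CG31915 and Lam, and their median was -0.0464. Coq6 rose by 0.43 and tomb fell by 0.55 (limma, adjusted p = 0.0411 and 0.023), while CG14015 (0.04) and Hel25E (-0.13) did not pass. These values argue against a fall of every gene on that side of Lam. On the other side none of the genes beyond Oscillin was tested. The probes of Oscillin and CG31915 share at most 5 and 7 bases in a row with the 60-base Lam probe, while the rest of Lam RNA was not searched, so that cross-hybridisation stays open. An effect of the lam double-stranded RNA on other transcripts and an effect of Lam loss on these genes stay open and were not tested.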

How the results depend on the processing

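All alternatives were chosen before the data were examined. The falls of Lam, Oscillin, Upf1, rhea and eIF3f1 and the rise of LamC kept their direction and stayed called under every alternative run, and of the values that lead a comparison 123 alternative values stayed on their side, 76 moved and 1 became called, which was the Msp300 difference in msp without unperturbed replicate 2 (0.90, adjusted p = 0.0451). Of the other results 3106 alternative values kept direction and call, 729 kept the direction and lost the call, 17 gained one, 6 moved and 1 reversed. That was the apoptosis and DNA damage list in lam, with a median of -0.0342 under median scaling, which moved the median of all genes by -0.20. The sign of the list median turned, but the list still lay above the median of all genes. Counts are given in the order koi, lam, msp, koi against lam, koi against msp and lam against msp where several are printed, and other causes were not tested.

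With no filter on dim probes the counts were 1, 103, 52, 40, 26 and 180, with 8 shared by lam and msp in direction. Fits of the 2 compared groups alone gave 1, 202, 151, 145, 345 and 443, and 18 shared. Normexp gave 9 (koi), 344 (lam), 243 (msp) and 206 (koi against lam), and 34 shared. Median scaling gave 8 (koi) and 155 (koi against msp), a trended robust prior 10 (koi), and array weights 226 (lam) and 708 (koi against msp). An added fold threshold of 2 left 180 (lam), 92 (msp), 116, 58 and 232, and that threshold with no test gave 52, 237, 141, 182, 99 and 276. The authors' value table gave 3, 560 and 377 for the knockdowns, with all 560 lam calls among the main calls. Without 1 array the counts ranged from 1 to 56 (koi), 242 to 895 (lam), 67 to 478 (msp), 86 to 656, 41 to 303 and 257 to 1399, from 16 to 174 shared, and from 0.0427 to 0.90 for the Msp300 difference in msp, where a group left with 1 array was assumed to vary like the others.

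The replicate numbers do not pair the samples: the 6 correlations of same-numbered deviations ran from -0.147 to 0.0722. With the replicate number as a block the counts were 1 (koi), 446 (lam), 277 (msp), 250, 160 and 800, and 55 shared. The slide row as a random block was not run, since no group spans both rows. No list passed with an estimated correlation (adjusted p from 0.747 to 0.813 for the 11 that passed with the preset one), while fry held for 2 of them in the tested direction and for 8 in its mixed form. Of the 70 list tests that camera did not call, fry passed in 3, immune genes and plasmatocyte markers in lam and crystal cell and lamellocyte markers in koi (adjusted p = 0.0276), and its mixed form in 30. Signal over background limits what can be read: 5991 probes were never detected, and folds of genes dim in 1 group are bounds.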

Other observations

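The genes named here belong to lists fixed before the data were examined, and were chosen from them after their values were seen, as were CG31099 and wun2. In lam cells pirk, an inhibitor of the Imd immune pathway, rose by 2.20 ± 0.14 (limma, adjusted p = 0.00079), and alphaTub67C, a tubulin of the female germline, not well above background in unperturbed cells, rose at least 2.02-fold (adjusted p = 0.00364). Immune genes as a list did not pass (16 members, median 0.22, camera adjusted p = 0.0881), although its members moved upward on balance (fry, adjusted p = 0.0106), and adjusted over the list alone 4 rose. In the nuclear pore list Sec13 (0.56) and mbo (0.42) rose, with the list at an adjusted p of 0.221. Lists of other tissues did not pass camera: in lam brp (neuronal, at least 1.94-fold), kon (muscle, 1.46) and Cp18 (ovary, 1.44) rose, the last 2 with 1 of 2 unperturbed arrays above background, and tomb (testis) fell by 0.55. The lists of brp, kon, Cp18 and tomb had adjusted p of 0.933, 0.669, 0.905 and 0.438. Of the fat body and gut list 3 members were detected, too few to test, and Yp3 rose at least 1.33-fold (adjusted p = 0.00866) while Yp2 (-0.01) and apolpp (-0.51, adjusted p = 0.106, 1 of 2 arrays above background in either group) did not pass. In the joint list of crystal cell and lamellocyte markers, PPO3 fell by 0.59 in lam (limma, adjusted p = 0.0085) while ItgaPS4 rose by 0.88 (adjusted p = 0.00182). Calls of Sec13, mbo, tomb, brp and Yp3 were lost without 1 to 7 of the 8 single arrays, with adjusted p up to 0.0930, 0.180, 0.107, 0.122 (brp, without lam replicate 1) and 0.0537, otherwise highest without unperturbed replicate 1.

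In the arrays labelled msp RNAi, a pair of spectrin genes of the actin list, beta-Spec (-0.64, limma, adjusted p = 0.0397) and kst (-0.44, adjusted p = 0.0406), fell, while the list did not pass (38 members, median -0.11, camera adjusted p = 0.11). The plasmatocyte receptor gene eater fell by 0.47 (adjusted p = 0.0365) and pirk rose by 0.73 (adjusted p = 0.0371). In the small RNA list Ars2 rose by 0.45 and Hen1 fell by 0.59, with the list at an adjusted p of 0.833. Each of these 6 calls was lost without 6 of the 8 single arrays, with adjusted p up to 0.242 (Hen1, without msp replicate 2). Cytoplasmic ribosomal protein genes, 79 of them tested, had medians of 0.04 (koi), -0.03 (lam) and -0.03 (msp) and did not pass in any knockdown (camera, adjusted p = 0.711, 0.438 and 0.474). The lists of chromatin silencing, actin, microtubules, mitosis, endoplasmic reticulum stress, ecdysone response, ribosome biogenesis, glycolysis and nuclear lamina did not pass in any knockdown either, and the lowest adjusted p among all tests that did not pass was 0.0848.

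CG31099 was above background on both unperturbed arrays and not well above background on any array of the 3 knockdowns. It was at least 2.22-fold lower in lam and 2.56-fold lower in msp (limma, adjusted p = 0.0174 and 0.0183), and at least 2.64-fold lower in koi, where it did not pass (adjusted p = 0.144). The lam call was lost without lam replicate 1 (adjusted p = 0.101), and the msp call without either msp array (adjusted p up to 0.130). The lipid phosphatase gene wun2 rose by 1.49 in lam and 1.5 in msp and stood at 0.83 in koi (adjusted p = 0.094).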
